A study of Homo sapiens with 16 samples.

How the data were processed

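Total RNA of HT1080 cells, a human fibrosarcoma line, was measured on 16 single-colour Illumina bead arrays carrying 24350 probes named by GI sequence numbers and 4 bacterial probes. Per the labels, cells received the thioxotriazole copper(II) complex A0 or cisplatin, each at 25 µM, or were left as controls. A0 was sampled after 1, 3, 6 and 12 h and cisplatin after 3, 6 and 12 h, with 2 arrays in each of the 8 groups. The labels give no time for the controls and do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

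The deposited array files hold 1 mean bead intensity per probe on a linear scale, not normalised between arrays, and a detection score from 0 to 1, per the file headers. They were made with BeadStudio 1.5.1.3, per the submitters' processing notes. A second table that the authors deposited holds processed intensity values. Set against the scanner values, each array of that table was a straight line of the same array's signal, with a scaling factor from 0.848 to 2.553 and a largest residual from 0.079 to 0.18. Its scale is therefore linear and background subtracted, while the name of the normalisation is not given in the sources used here. The median of its columns is 12.8 for control 1 and 12.2 for control 2, and it served only as an alternative.

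Signals were corrected and normalised with neqc in limma 3.58.1 under R 4.3.3. This step estimates background from the detection scores, adds an offset of 16, applies quantile normalisation and takes log2. A probe was tested if its detection p (1 minus the score) was at most 0.01 on both arrays of at least 1 group, which left 9293 of the 24350 probes. The array number limits the precision: between 7626 and 9640 probes were detected per array, the median bead number per probe was 41 to 42, and the median signal ran from 93.5 to 130.7. One linear model over all 16 arrays gave each group its mean, with 8 residual degrees of freedom and 5.7 prior degrees of freedom, and limma's moderated test gave 13 comparisons at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are differences of the normalised log2 values. For A0 12 h against control, data were simulated with 200 changed probes among 9293 and the same spread of a probe in every group. The test found 4.11% of probes changed 1.5-fold, 42.9% of those changed 2-fold and 98.6% of those changed 4-fold. Of its calls, 4.88% were false. The adjusted threshold depends on how many probes change, so these shares hold only for that setting.

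The effect spread beyond error is the root of the mean squared log2 fold change minus the mean squared standard error. A probe undetected on both arrays of a group has only a bound there, so its fold is given as "at least", from the bright group's mean against the lowest detected signal of the dim arrays or the probe's own signal, whichever was higher. Comparisons that share the control arrays were set against 100 simulated sets of unchanged groups and against the overlap of independent lists.

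The files do not pair the GI numbers with gene names, and 0 of them matched the reference table, so no gene is named. Suffixes of the probe names divide the tested probes into 7659 for genes with a single transcript, 546 for 1 of several transcript variants and 1088 for all variants of a gene. The 20 gene lists, with 542 entries, and the genes to be reported in every group were fixed before the data were examined, as were the comparisons, the test and most alternatives, but 0 list entries could be matched and the lists were not tested. The rule for named features took those with the largest rise and the largest fall whose arrays did not overlap between groups. Only the first riser and the first faller at 12 h of each drug are printed, 4 in all. The choice of 1 probe per gene could not be made either, so each probe was tested. Alternatives covered background correction, scaling, the filter, the fold threshold, the variance model, array weights, a block for the replicate number, the arrays in the model and leaving out each array. A block for the slide was not run because the files used here name no slide.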

Results

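The 16 arrays followed HT1080 fibrosarcoma cells through 12 h of exposure to A0, a copper(II) complex, or to cisplatin, a platinum drug that binds DNA. There were 2 control arrays, 8 A0 arrays and 6 cisplatin arrays. Replicates correlated at 0.961 to 0.984 across the 9293 tested probes, and the SD of the difference between replicates ran from 0.328 for A0 1 h to 0.511 on the log2 scale for A0 6 h. The first principal component held 33.1% of the variance and ran from cisplatin 12 h (-43.9 and -37.2) to A0 12 h (26.4 and 29.8). The controls lay apart on the third component, which held 11.8% (28 and 31).

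The first question was how cells given A0 differed from control over time. No control array was matched in time, so comparisons with control cannot separate the drug from handling or culture time. At 1 h, 162 probes were higher than in control and 92 lower, with a median of 2.56-fold among the risers and 2.28-fold among the fallers. At 3 h, 92 probes were higher and 27 lower, at 6 h 184 and 195, and at 12 h 585 and 774, or 14.6% of those tested. The order of the counts before 12 h depended on the estimate of spread. With only the arrays of the groups compared, the counts at 1, 3, 6 and 12 h were 952, 199, 49 and 1286. With array weights they were 1307, 551, 389 and 1701. The spread of effects beyond error was 0.392, 0.373, 0.435 and 0.582 on the log2 scale at these times. It takes off the same shared error at each time. Replicates differed with an SD of 0.328 at A0 1 h and 0.511 at A0 6 h, so the order of these values before 12 h is not settled either. By measured values the probe GI_42822885-S rose the most at 12 h, though 122 of the 585 risers were undetected on both control arrays. Its log2 signal went from 5.22 ± 0.53 (SD, n = 2) in control to 9.64 ± 0.24, 11.58 ± 0.68, 13.53 ± 0.20 and 14.02 ± 0.22 at 1, 3, 6 and 12 h. The log2 fold change was 4.41 at 1 h (SE 0.727, limma adjusted p = 0.0135) and 8.79 at 12 h (adjusted p = 8.38e-06), and 1 of the 2 control arrays detected the probe. The probe GI_42476202-S was taken as the faller by measured values, but 269 of the 774 fallers were undetected on both A0 12 h arrays, so its rank is not firm. It fell by 2.80 on the log2 scale at 12 h (SE 0.39, limma adjusted p = 0.000504), from 10.22 ± 0.16 to 7.42 ± 1.11 (SD, n = 2). It had fallen by 1.61 at 6 h (adjusted p = 0.0376). With each array left out in turn the 12 h calls of both probes against control held. The 1 h call of GI_42822885-S was lost without either control or either A0 1 h array, and the 6 h call of GI_42476202-S without either control, either A0 1 h array or either A0 6 h array, with an adjusted p of up to 0.142 and 0.197.

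The early and the late lists of A0 overlapped in part. Of the 162 probes higher at 1 h, 65 were also called higher at 3 h, 71 at 6 h and 52 at 12 h, where independent lists would share 1.6, 3.21 and 10.2, and their median log2 fold change went from 1.35 to 1.14, 0.99 and 0.56. The lists share the control arrays, which raises such overlaps, and the 1 h list itself shrank to 5 and 2 probes without control 1 and control 2. Set directly against A0 1 h, 72 of these 162 probes were lower at 12 h and 11 were higher. A0 3 h differed from A0 1 h at 0 probes in limma's test, with 361 probes at an unadjusted p under 0.05 where 465 come by chance. The shared spread may be too wide for this pair, whose replicates differed with an SD of 0.328 and 0.409 against up to 0.511 elsewhere. The 0 therefore does not show that nothing changed from 1 to 3 h. Choosing the 162 probes by their 1 h values lifts their 1 h median, so part of their decline comes from the choice. Conversely, of the 585 probes higher at 12 h, 148 were higher at 6 h, 65 at 3 h and 52 at 1 h, against 11.6, 5.79 and 10.2 for independent lists. In all, 1565 probes passed the threshold at 1 or more times, 711 higher and 854 lower, and 0 in both directions.

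Early counts moved when 1 array was left out. A compared group left with 1 array loses power, so a fall does not mark that array as divergent. Arrays of other groups moved the counts only through the shared estimate of spread. Against control, the 1 h count of 254 became 5 and 2 without control 1 and control 2, 7 and 9 without A0 1 h replicate 1 and 2, and 416 without either A0 6 h array. The 3 h count of 119 became 11, 10 and 9 without control 1, control 2 and A0 3 h replicate 1, 50 without either A0 1 h array, 68 without either cisplatin 6 h array and 252 without either A0 6 h array. The 6 h count of 379 became 54, 56 and 151 without control 1, control 2 and A0 6 h replicate 1, and the 12 h count of 1359 became 563, 479 and 582 without control 1, control 2 and A0 12 h replicate 2. With 75th percentile centring, which moved the median of all probes by 0.183 at 12 h, 783 probes were higher and 503 lower at 12 h and 234 and 143 at 6 h, so no majority direction is given for those times.

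**Figure D1:**
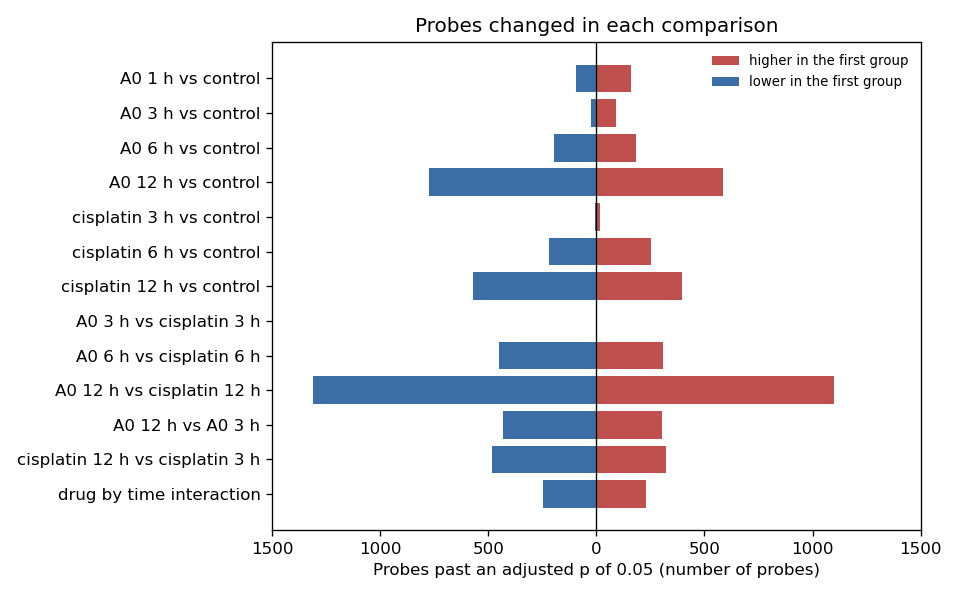
Bars to the right count probes higher, and bars to the left probes lower, in the first group of each comparison at an adjusted p of 0.05. The longest bars belong to A0 12 h against cisplatin 12 h, with 1099 higher and 1310 lower, and the shortest to the 3 h comparison of the drugs, with 1 in each direction.

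The second question was how cells given cisplatin differed from control over time, with the same limit of controls not matched in time. At 3 h, 19 probes were called higher than in control and 6 lower, with a spread of effects beyond error of 0.317. An unadjusted p under 0.05 was reached by 1316 probes where 465 come by chance, against 1529 for A0 at 3 h, so the few calls do not show that few transcripts changed. At 6 h, 252 were higher and 221 lower, and at 12 h, 395 were higher and 572 lower, or 10.4% of those tested, with spreads of 0.408 and 0.485. By measured values the probe GI_24475878-S rose the most at 12 h, though 55 of the 395 risers were undetected on both control arrays. It went from 6.50 ± 0.44 to 9.47 ± 0.02 (SD, n = 2), a log2 fold change of 2.96 (SE 0.385, limma adjusted p = 0.000363), after 1.47 at 6 h (adjusted p = 0.0439). The probe GI_37545618-S was taken as the faller by its measured value, which gives no rank because it lies below detection at 12 h. Its log2 signal went from 8.04 ± 0.21 in control to 6.43 ± 0.13 at 6 h and to 4.90 ± 0.25 at 12 h (SD, n = 2). Neither 12 h array detected it, so it was at least 5.71-fold lower than in control. The limma adjusted p of 2.4e-05 belongs to the measured log2 change of -3.14, and the bound was not tested. With each array left out in turn the 12 h calls of both against control held. The 6 h call of GI_24475878-S was lost without either control or either array of A0 1 h, A0 3 h, cisplatin 6 h or cisplatin 12 h, with an adjusted p of up to 0.3. Of the 252 probes higher at 6 h, 151 were also higher at 12 h, and of the 221 lower at 6 h, 175 were lower at 12 h, against 10.7 and 13.6 for independent lists. Both lists use the same control arrays, so part of that overlap may come from them. In all, 1117 probes passed the threshold at 1 or more times, 499 higher, 617 lower and 1 in both directions.

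The cisplatin counts also moved when 1 array was left out, with the same loss of power in a compared group. The 3 h count of 25 became 2, 0, 1 and 6 without control 1, control 2, cisplatin 3 h replicate 1 and cisplatin 3 h replicate 2, 9 without either A0 1 h array, 8 without either A0 3 h array and 56 without either A0 6 h array. The 6 h count of 473 became 48, 32, 106 and 66 without control 1, control 2, cisplatin 6 h replicate 1 and cisplatin 6 h replicate 2, and the 12 h count of 967 became 368, 291 and 342 without control 1, control 2 and cisplatin 12 h replicate 1.

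**Figure D2:**
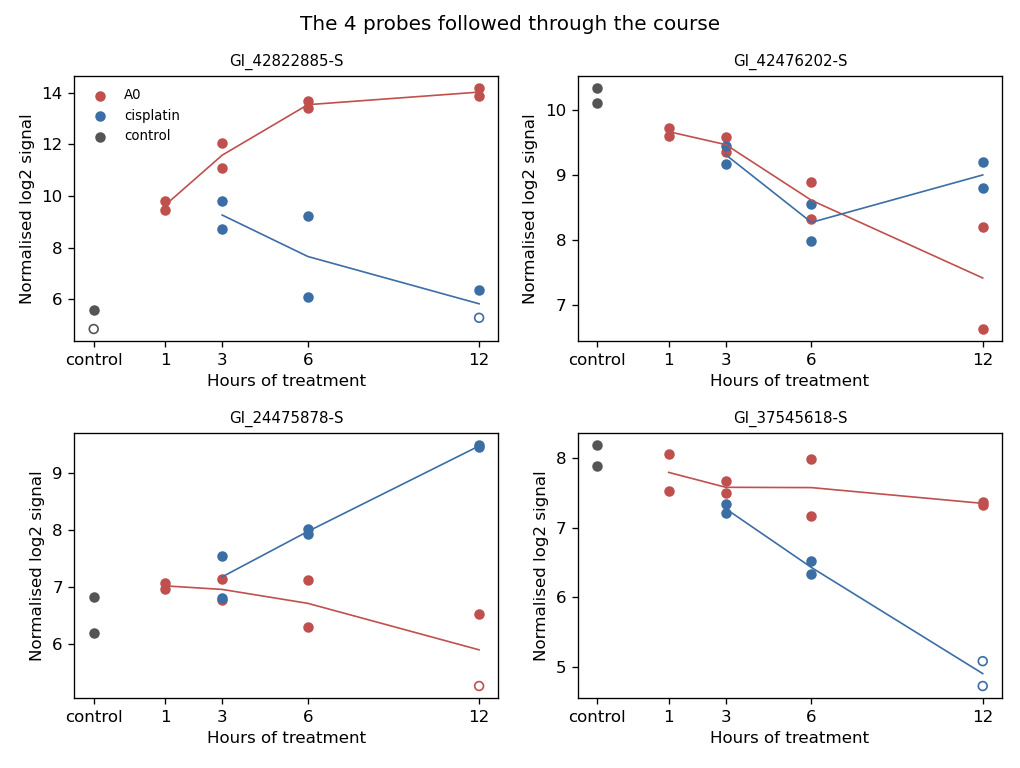
Each panel shows the normalised log2 signal of 1 probe against hours of treatment; points are single arrays, lines join the means of 2 arrays, and open points mark arrays that did not detect the probe. GI_42822885-S reaches 14.02 at A0 12 h and 5.83 at cisplatin 12 h, while GI_24475878-S reaches 9.47 at cisplatin 12 h and 5.89 at A0 12 h.

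The third question was where the 2 drugs differ at the same time. At 3 h they differed at 2 probes, 1 in each direction, with 508 probes at an unadjusted p under 0.05 where 465 come by chance. At 6 h, 306 probes were higher with A0 and 450 lower, and at 12 h, 1099 were higher and 1310 lower, or 25.9% of those tested. The spread of effects beyond error between the drugs was 0.153, 0.477 and 0.717. The error taken off was the one shared by all groups. Replicates at 3 h differed with an SD of 0.409 for A0 and 0.481 for cisplatin, so the 3 h value may be largely their error. The 3 h value was -0.147 without A0 3 h replicate 1 (a negative sign marks fold changes smaller than their error), 0.271 without A0 3 h replicate 2 and 0.254 without cisplatin 3 h replicate 1. The probe GI_42822885-S was 2.32 higher with A0 than with cisplatin at 3 h (adjusted p = 0.571), 5.87 higher at 6 h (adjusted p = 0.000734) and 8.19 higher at 12 h (SE 0.727, limma adjusted p = 1.19e-05). With cisplatin it had also risen at 3 h, by 4.04 on the log2 scale (adjusted p = 0.0361). Its 2 arrays at 6 h read 9.21 and 6.10. At 12 h it was 0.60 above control (adjusted p = 0.669), with 1 of 2 arrays detecting it in each of these groups. Differences from cisplatin 12 h thus rest in part on a signal below detection. That 3 h call was lost without either control or either array of A0 1 h, A0 3 h, A0 12 h or cisplatin 3 h, with an adjusted p of up to 0.376. At 12 h the probe GI_24475878-S differed by -3.58 between A0 and cisplatin (adjusted p = 3.81e-05) and was -0.61 from control with A0 (adjusted p = 0.33). The probe GI_42476202-S was also lower with cisplatin at 6 h, at -1.95 on the log2 scale (adjusted p = 0.0159), where the drugs differed by 0.34 (adjusted p = 0.667). At cisplatin 12 h it stood at -1.22 (adjusted p = 0.063), and this call turned with the setting. Its limma adjusted p was 0.0399 with the replicate number as a block and 0.0361 with a trended and robust variance. With 75th percentile centring it was 0.0733 and with the deposited processed values 0.184. That 6 h call was lost without either control or cisplatin 6 h replicate 2, with an adjusted p of up to 0.126. At 12 h it was 1.58 lower with A0 than with cisplatin (adjusted p = 0.00923), a call lost without A0 12 h replicate 2 (a difference of -0.798, adjusted p = 0.109) and without cisplatin 12 h replicate 2 (adjusted p = 0.0624). The probe GI_37545618-S, undetected at cisplatin 12 h, was at least 3.54-fold higher with A0 (adjusted p = 3.93e-05 for the measured log2 difference of 2.45).

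The controls enter these counts through the shared estimate of spread, the normalisation and the filter, and leaving out an array repeated only the test. The 3 h count became 1, 6 and 1 without A0 3 h replicate 1, A0 3 h replicate 2 and cisplatin 3 h replicate 2, and 8 without either A0 6 h array. The 6 h count of 756 became 425, 380 and 178 without A0 6 h replicate 1, cisplatin 6 h replicate 1 and cisplatin 6 h replicate 2. The 12 h count of 2409 became 1446 and 1505 without A0 12 h replicate 2 and cisplatin 12 h replicate 1. With 75th percentile centring 1320 probes were higher with A0 and 978 lower at 12 h.

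**Figure D3:**
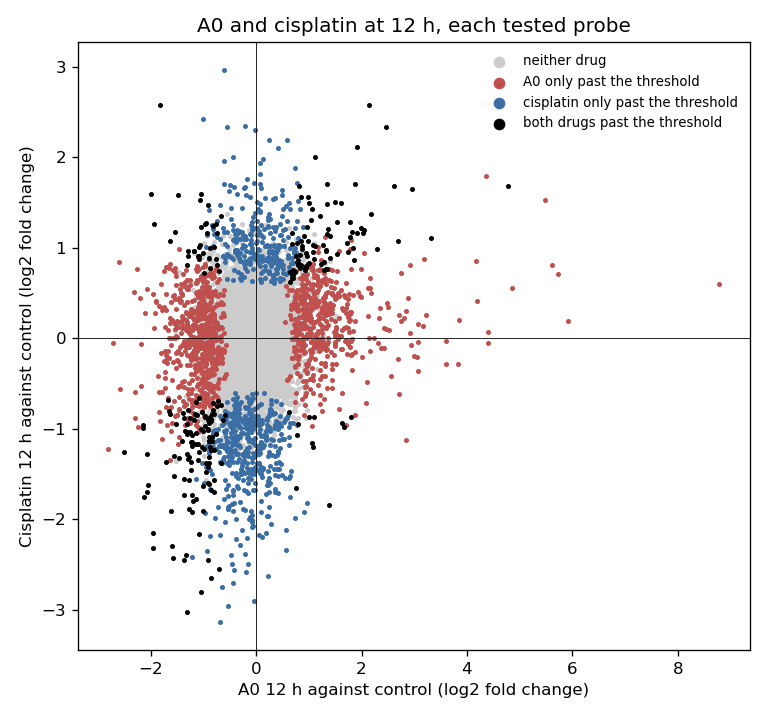
Each point is 1 of the 9293 tested probes, with its log2 fold change against control at 12 h of A0 on the horizontal axis and of cisplatin on the vertical axis, coloured by which drug passed the adjusted p of 0.05. Probes past the threshold in both drugs lie in the same direction for 198 and in opposite directions for 48.

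Calls shared by the drugs were counted at each matched time. At 3 h, 15 probes were higher and 2 lower with both drugs; at 6 h, 48 and 29; at 12 h, 86 and 112. Independent lists of these sizes would share 0.188 and 0.0174 at 3 h, 4.99 and 4.64 at 6 h, and 24.9 and 47.6 at 12 h. Opposite calls numbered 1, 6 and 48, against 0.115, 9.66 and 68.9 for independent lists, and at 12 h they comprised 12 probes higher with A0 and lower with cisplatin and 36 the other way. The covariance of the fold changes across probes was 0.147, 0.104 and 0.0682, against a mean of 0.0395 for unchanged groups compared with the same controls. Their Pearson correlation was 0.746, 0.404 and 0.189, against a simulated mean of 0.5; probes are not independent replicates. Part of each excess may come from the shared controls. With a separate control array for each drug the covariances were 0.111 or 0.129 at 3 h, 0.0804 or 0.0717 at 6 h and 0.0424 or 0.0392 at 12 h. Unchanged groups simulated in this way, with no deviation common to both control arrays, lay between -0.00262 and 0.00296. The shared calls were then 2 or 0, 1 or 2 and 25 or 31, but leaving out control 1 or control 2 while both drugs used the other already gave 2 or 0, 6 or 2 and 36 or 34, so these counts do not measure the sharing. They also became 7 at 3 h without either A0 1 h array, 2 and 6 without A0 3 h replicate 1 and 2, 0 and 3 without cisplatin 3 h replicate 1 and 2, and 39 without either A0 6 h array. At 6 h they became 40, 21 and 29 without A0 6 h replicate 1, cisplatin 6 h replicate 1 and cisplatin 6 h replicate 2, and at 12 h 100 and 70 without A0 12 h replicate 2 and cisplatin 12 h replicate 1.

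The last question was how each drug's profile moved between 3 and 12 h, and whether these movements differed. With A0, 305 probes were higher at 12 h than at 3 h and 432 lower. With cisplatin, 322 were higher and 484 lower. The interaction of drug and time passed the threshold at 478 probes, 231 with a higher value for A0 and 247 with a lower one. Scaling turned 2 of these splits. With 75th percentile centring 329 probes were higher and 225 lower for A0, but 363 and 379 with the deposited processed values, and the interaction gave 218 and 155 or 283 and 169. For cisplatin most called probes stayed lower, at 249 and 410 or 183 and 473. The interaction passed the threshold for GI_42822885-S, at 5.87 on the log2 scale (SE 1.028, limma adjusted p = 0.00732), and for GI_24475878-S at -3.36 (adjusted p = 0.0053). It also passed for GI_37545618-S, at a measured 2.14 (adjusted p = 0.00735). Since that probe was undetected at cisplatin 12 h, only a bound of 1.51 or more can be given, and the bound was not tested. GI_42476202-S stood at -1.74 (adjusted p = 0.0856). The count of 737 for A0 became 173, 251 and 204 without A0 3 h replicate 1, A0 3 h replicate 2 and A0 12 h replicate 2, and that of 806 for cisplatin became 206 and 292 without cisplatin 3 h replicate 1 and cisplatin 12 h replicate 1. The interaction count became 244, 209, 280, 300 and 295 without A0 3 h replicate 1, A0 3 h replicate 2, A0 12 h replicate 2, cisplatin 3 h replicate 1 and cisplatin 12 h replicate 1.

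**Figure D4:**
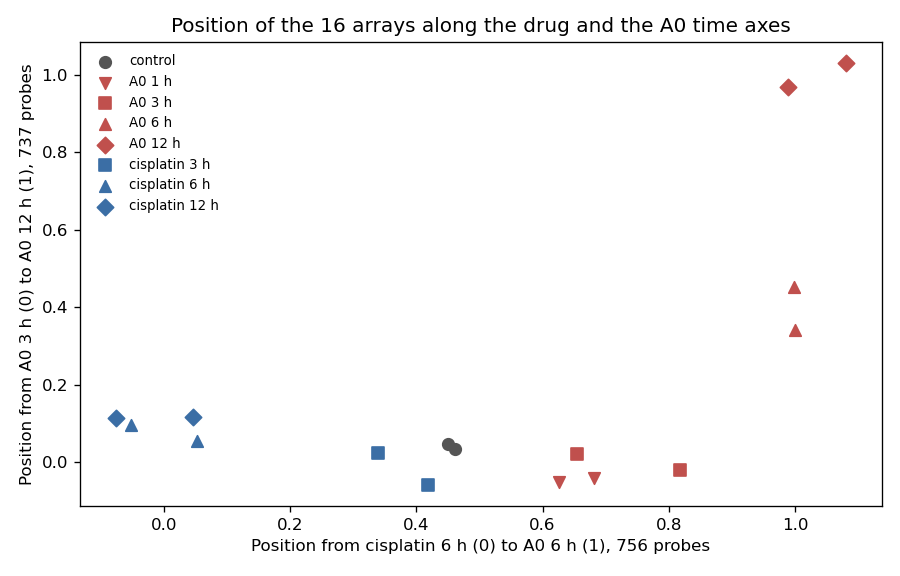
Each point is 1 array, placed horizontally between the means of cisplatin 6 h (0) and A0 6 h (1) and vertically between the means of A0 3 h (0) and A0 12 h (1), over the probes called in each of these comparisons. The controls sit at 0.45 and 0.462 on the horizontal axis, the A0 3 h arrays at 0.817 and 0.655 and the cisplatin 3 h arrays at 0.419 and 0.339.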

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

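The test of exchanged labels at 3 h and the axes made without 1 array were chosen only after related results had been seen.

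The drugs' effects differed by a direct test at 2 probes at 3 h, 756 at 6 h and 2409 at 12 h. A0 at 12 h differed from A0 at 3 h at 737 probes, and cisplatin at 12 h from cisplatin at 3 h at 806. The change between these times differed between the drugs at 478 probes, among them GI_42822885-S by 5.874 on the log2 scale, GI_24475878-S by -3.355 and GI_37545618-S, undetected at cisplatin 12 h, by at least 1.513. The bacterial probe lysA, outside the main measurement, was detected on 2 of the 16 arrays, A0 12 h replicate 2 (131.3) and cisplatin 6 h replicate 2 (120.8), against 122.1 and 96.7 on the controls.

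Both controls stood apart from all 14 treated arrays: 401 probes differed between the treated groups and control, 211 higher and 190 lower. Independent chance values of the 2 shared control arrays would leave the covariance of the drugs' fold changes within the 100 simulated values. It exceeded them at 3 of 3 matched times. The simulation used only the spread between replicates. A chance deviation common to both control arrays was not in it and is not excluded. Array brightness as a covariate gave 558 probes, including all 401. Handling or culture time cannot be told apart from a response common to both drugs, because 0 control arrays were matched in time, so a shared early response to both drugs remains a hypothesis.

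The 2 A0 6 h arrays lay 0.11 apart between A0 3 h (0) and A0 12 h (1), the widest replicate distance of the 8 groups, but their order turned on axes made without 1 array: replicate 2 minus replicate 1 was -0.087 and 0.066 without A0 3 h replicate 1 and 2, and 0.155 and -0.078 without A0 12 h replicate 1 and 2. Array brightness cannot be told apart as a cause, since the corrected distance of 0.0621, above the 0.0412 of the next group, rests on an order that was not stable. Across the 8 groups distance and brightness difference had a Pearson r of 0.575 (exact permutation p = 0.138, two-sided; 0.528 without the 2 farthest groups) and a Spearman rho of 0.571 (exact permutation p = 0.151), the only such relation computed. Exchanged labels with A0 12 h or A0 3 h would put an array of those groups on the wrong side of the A0 6 h midpoint, and 0 of 4 were when each was placed on an axis made without it, at 0.144 and 0.188 for A0 3 h and 0.716 and 0.791 for A0 12 h. No biological explanation was tested.

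A0 and cisplatin differed at few probes at 3 h. Whether 1 divergent array caused this cannot be told apart from lost power. The highest count with 1 of the 4 arrays left out was 6. At 6 and 12 h, leaving out an array of the 2 groups compared at that time lowered the count, while arrays of other groups could raise it. The spread beyond error rose to 0.271 without A0 3 h replicate 2 and to 0.254 without cisplatin 3 h replicate 1. The threshold alone was predicted to leave effects as wide as against control. The spread beyond error was 0.153 between the drugs against 0.373 for A0 3 h against control. With 1 of the 16 arrays left out it ran from -0.147 (without A0 3 h replicate 1) to 0.271 between the drugs and from 0.238 to 0.476 against control, with the first value smaller in each of the 16 fits. Effects between the drugs were thus smaller than against control. The values against control also hold the difference of both controls from all treated arrays, which cancels between the drugs. The threshold may still have hidden smaller drug differences. Exchanged labels would mix the groups on the axis from cisplatin 6 h to A0 6 h, yet both cisplatin 3 h arrays lay at least 0.237 below both A0 3 h arrays. An effect of culture time common to both 3 h groups cancels between the drugs. In the values against control it stays open because 0 control arrays were matched in time.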

How the results depend on the processing

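The brightness covariate and the removal of both A0 6 h arrays were chosen after seeing the data. Over all alternatives, 112 counts, and 179 with 1 array left out, stayed within 1.5 times the values reported, and 83 and 77 did not. For the 4 probes named, in the 12 h comparisons, 317 refitted values kept their side of the threshold and 0 called ones reversed. The exceptions were 2 values of GI_42476202-S that lost their call and 8 that gained one, all with the direction kept. These probes were picked for large changes and say nothing of others. The uncalled value of GI_24475878-S at A0 12 h against control went from -0.612 to 0.022 without A0 12 h replicate 2. Signals near background limit what can be seen, since under a detection p of 0.01 at most 9640 of 24350 probes were detected on an array. The test found 42.9% of simulated 2-fold changes for A0 12 h against control, with 200 changed probes. That share was not split by signal. The adjusted threshold depends on how many probes change, and 1359 were called in the data, so it is not the sensitivity reached there. Leaving out an array kept the normalisation and the filter of all 16. Leaving 1 array of a pair assumes that the lone array varies like the other groups. The gene list alternatives and a slide block were not run, and testing every probe is what was done throughout. Except where a setting tests fewer probes or uses fewer arrays, the cause was not tested.

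Without background correction, counts were 452 for A0 1 h against control, 340 for A0 3 h against control, 87 for cisplatin 3 h against control, 11 for A0 3 h against cisplatin 3 h, 66 for shared calls at 3 h and 120 for shared calls at 6 h. With 75th percentile centring, the count was 8 for A0 3 h against cisplatin 3 h. With the deposited processed values, counts were 103 for A0 1 h against control, 57 for A0 3 h against control, 12 for cisplatin 3 h against control, 4 for A0 3 h against cisplatin 3 h and 6 for shared calls at 3 h. Without the filter, counts were 101 for A0 1 h against control, 41 for A0 3 h against control, 216 for A0 6 h against control, 6 for cisplatin 3 h against control, 283 for cisplatin 6 h against control, 318 for the interaction, 5 for shared calls at 3 h and 43 for shared calls at 6 h. With probes detected on all 16 arrays, a smaller set, counts were 234 for A0 3 h against control, 46 for cisplatin 3 h against control, 5 for A0 3 h against cisplatin 3 h, 488 for A0 6 h against cisplatin 6 h, 1558 for A0 12 h against cisplatin 12 h, 430 for A0 12 h against A0 3 h, 272 for the interaction and 40 for shared calls at 3 h. With a threshold of at least 2-fold, counts were 825 for A0 12 h against control, 590 for cisplatin 12 h against control, 1450 for A0 12 h against cisplatin 12 h, 520 for cisplatin 12 h against cisplatin 3 h and 84 for shared calls at 12 h. With a trended and robust variance, counts were 416 for A0 1 h against control, 288 for A0 3 h against control, 66 for cisplatin 3 h against control, 7 for A0 3 h against cisplatin 3 h and 52 for shared calls at 3 h. With array weights, counts were 1307 for A0 1 h against control, 551 for A0 3 h against control, 1099 for cisplatin 6 h against control, 1 for A0 3 h against cisplatin 3 h, 299 for cisplatin 12 h against cisplatin 3 h, 264 for the interaction and 128 for shared calls at 6 h. With only the arrays of the groups compared, fewer arrays, counts were 952 for A0 1 h against control, 199 for A0 3 h against control, 49 for A0 6 h against control, 7 for cisplatin 3 h against control, 992 for cisplatin 6 h against control, 0 for A0 3 h against cisplatin 3 h, 207 for A0 6 h against cisplatin 6 h, 1550 for A0 12 h against cisplatin 12 h, 167 for A0 12 h against A0 3 h, 219 for cisplatin 12 h against cisplatin 3 h, 171 for the interaction, 7 for shared calls at 3 h, 25 for shared calls at 6 h and 122 for shared calls at 12 h. With the brightness covariate, counts were 279 for A0 3 h against control, 667 for A0 6 h against control, 39 for cisplatin 3 h against control, 9 for A0 3 h against cisplatin 3 h and 125 for shared calls at 6 h. With both A0 6 h arrays removed, counts were 416 for A0 1 h against control, 252 for A0 3 h against control, 56 for cisplatin 3 h against control, 8 for A0 3 h against cisplatin 3 h and 39 for shared calls at 3 h. With A0 against control 1 and cisplatin against control 2, counts were 2 for shared calls at 3 h, 1 for shared calls at 6 h and 25 for shared calls at 12 h. With A0 against control 2 and cisplatin against control 1, counts were 0 for shared calls at 3 h, 2 for shared calls at 6 h and 31 for shared calls at 12 h.

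The labels do not say what the shared replicate numbers mark. The numbers were not used as pairs because not every correlation of their deviations passed 0.1. The correlations ran from -0.257, for control and cisplatin 3 h, to 0.376, with 18 of 28 pairs over 0.1. In every treated group replicate 2 had the higher 99th percentile signal, as in cisplatin 3 h (2190.4 and 4108.4). In the controls replicate 1 had the higher one (3731.3 and 3308.3). By these deviations, 14 of 16 arrays correlated best with an array of their own number. Deviations from a group's mean are mirror images within the group, so each array's result fixes that of its partner. The 14 of 16 are therefore not separate outcomes. These matches only hint, from the data and not the design, at a structure that the counts reported ignore. With the replicate number as a block, counts were 556 for A0 1 h against control, 405 for A0 3 h against control, 658 for A0 6 h against control, 116 for cisplatin 3 h against control, 714 for cisplatin 6 h against control, 4 for A0 3 h against cisplatin 3 h, 86 for shared calls at 3 h and 135 for shared calls at 6 h.

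With 1 array left out in turn, counts ranged from 2 to 416 for A0 1 h against control, from 9 to 252 for A0 3 h against control, from 54 to 549 for A0 6 h against control, from 479 to 1461 for A0 12 h against control, from 0 to 56 for cisplatin 3 h against control, from 32 to 568 for cisplatin 6 h against control, from 291 to 1044 for cisplatin 12 h against control, from 1 to 8 for A0 3 h against cisplatin 3 h, from 178 to 832 for A0 6 h against cisplatin 6 h, from 1446 to 2508 for A0 12 h against cisplatin 12 h, from 173 to 906 for A0 12 h against A0 3 h, from 206 to 932 for cisplatin 12 h against cisplatin 3 h, from 209 to 560 for the interaction, from 0 to 39 for shared calls at 3 h, from 2 to 105 for shared calls at 6 h and from 34 to 221 for shared calls at 12 h.

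Scaling moved the share of higher calls by over 10 percentage points in places. The shares reported were 63.8% for A0 1 h against control, 77.3% for A0 3 h against control, 48.5% for A0 6 h against control, 43% for A0 12 h against control, 76% for cisplatin 3 h against control, 50% for A0 3 h against cisplatin 3 h, 45.6% for A0 12 h against cisplatin 12 h, 41.4% for A0 12 h against A0 3 h, 40% for cisplatin 12 h against cisplatin 3 h and 48.3% for the interaction. Without background correction they were 52.9% for A0 3 h against control, 64.4% for cisplatin 3 h against control and 72.7% for A0 3 h against cisplatin 3 h. With 75th percentile centring they were 62.1% for A0 6 h against control, 60.9% for A0 12 h against control, 87.5% for A0 3 h against cisplatin 3 h, 57.4% for A0 12 h against cisplatin 12 h, 59.4% for A0 12 h against A0 3 h and 58.4% for the interaction. With the deposited processed values they were 79.6% for A0 1 h against control, 62.4% for A0 6 h against control, 60.6% for A0 12 h against control, 75% for A0 3 h against cisplatin 3 h, 58.9% for A0 12 h against cisplatin 12 h, 27.9% for cisplatin 12 h against cisplatin 3 h and 62.6% for the interaction. The median of all probes moved most for A0 12 h against control, by 0.183 with 75th percentile centring and by 0.197 with the deposited values. The shares of A0 12 h are therefore not read as a majority direction.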

Other observations

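The tests of carried-over RNA were chosen only after related results had been seen.

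Probes for different kinds of transcript differed in how often they changed. Of the 546 tested probes for 1 of several transcript variants, 11.7% were called at A0 12 h and 6.96% at cisplatin 12 h. Single-transcript probes matched on brightness were called at 15.8% and 10.7%, a difference of -3.74 percentage points for cisplatin (permutation p = 0.012 for A0 and 0.0066 for cisplatin, two-sided, adjusted p = 0.024 for both over 4 comparisons). Of the 1088 probes for all variants of a gene, 12.3% were called for A0 against a matched 15% (permutation p = 0.021, adjusted p = 0.028) and 10% for cisplatin against 10.8% (permutation p = 0.43). The permutations treat probes as independent, which genes regulated together are not. The difference may reflect weaker regulation of single variants or a property of those probes, and no test run here separates the 2.

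Of the 92 probes raised at A0 3 h, 15 were also called higher at cisplatin 3 h. If a small share of A0-treated RNA had been carried into the cisplatin 3 h samples, 1 share under 20% would explain the cisplatin 3 h levels of the set, called or not. The share needed had a median of 65.4% and an interquartile range from 36.8% to 84%. Since the choice of these probes and the share both use the same control arrays, the share was also taken over 92 probes chosen with 1 control array and measured from the other. It had a median of 62.8% (33.2% to 82.1%) measured from control 2 and of 68% (35.1% to 81.6%) measured from control 1. A share under 20% alone therefore did not account for the set as measured. Both controls stood apart from all treated arrays, and a deviation common to both would raise the share needed on each of these measures. The test therefore cannot exclude a small share beside such a deviation, and a larger share was not examined.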
